A study of Mus musculus with 8 samples.

How the data were processed

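Total RNA from Csk-deficient mouse embryonic fibroblasts (C57BL/6J) transfected with empty vector, c-Src, Csk and c-Src, or Csk was labelled with Cy3 and hybridised to Agilent one-color mouse microRNA arrays, from 100 ng of RNA with integrity numbers above 9, per the labels' protocols. There were 4 groups of 2 arrays, which the labels call biological replicates; the series description says only that samples were run in duplicate, so how far the cells of a group were grown apart is not given in the sources used here. Per the file headers, the authors extracted the deposited spot intensity values with Agilent Feature Extraction 9.5.3.1, with a fitted spatial background subtracted and no scaling between arrays. The deposited gene-level intensity is the software's total gene signal, the sum over the probes of a microRNA, per the file headers. The deposited series table holds that intensity unscaled and with values under 1 set to 1, which was checked on 672 of 672 entries per array within a relative tolerance of 1e-05. All arrays lay on 1 slide and came from 1 scan, with each group in its own slide column and each replicate number in its own row, so the slide column and the group cannot be told apart. In the values of Csk array 1 the processed signal had been rounded, by at most 0.493% against an unrounded column of the same array.

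Each array held 13715 spots, 13000 of them not controls, and 1857 probes for 611 mouse and 39 viral names; 359 names had 2 probes, 274 had 4, 13 had 3 and 4 had 1. Of the spots, 0 were saturated. For each array the processed signal of spots not marked as outliers was averaged over the spots of a probe, summed over the probes of a microRNA, and divided by the 75th percentile over the 187 microRNAs detected on all 8 arrays (611.9 to 805.7 in signal units). Values under a floor of 0.01933 (log2 -5.69), the median over arrays of the 5th percentile of detected microRNAs, were set to it, and log2 was taken. The 243 mouse microRNAs detected on both arrays of at least 1 group were tested and 368 were not; 6 of those tested lay at the floor on all arrays. Where no array of a group detected a microRNA, its fold is given as a lower bound, against the higher of the floor and its own signal on each array of that group.

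The design, the named microRNAs, the lists and most of the alternatives were chosen before the data were examined. limma 3.58.1 in R 4.3.3 fitted group means over the 8 arrays with empirical Bayes moderation (4 residual and 5.09 total degrees of freedom), and microRNAs with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called. The spread is pooled over the groups because 2 arrays per group leave too few residual degrees of freedom alone. An exact test of 2 arrays against 2 cannot go below p = 0.333. The comparisons were c-Src with mock, Csk+c-Src with c-Src, Csk with mock, Csk+c-Src with Csk, Csk+c-Src with mock, and the interaction. Named in the text are the 10 largest rises and falls past the threshold without overlap of arrays in each of the first 2 comparisons, the 3 largest of each in the others, miR-99a, miR-27b, miR-542-3p, miR-21, miR-145, miR-31 and miR-210 whatever their result, and up to 4 members per list. miR-206, miR-486 and miR-126-3p in the last 4 of these, and miR-15b and miR-16 in Csk with mock and Csk+c-Src with Csk, were added after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

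The 24 lists were miR-17~92 and paralogous clusters, let-7, miR-99, miR-100 and miR-125 (1 list), the X-linked cluster of miR-322, miR-503, miR-542 and miR-450, miR-23 with miR-27 and miR-24, miR-15 with miR-16, miR-29, miR-30, miR-34, miR-181, miR-221 with miR-222, miR-143 with miR-145, miR-199 with miR-214, miR-200, miR-203 with miR-205, muscle, blood cell, endothelial, neural, embryonic stem cell clusters, miR-96 with miR-182 and miR-183, the Dlk1-Dio3 cluster, the Sfmbt2 cluster, and study microRNAs. limma's camera with a preset correlation of 0.01 compared each list of at least 3 tested members with the other microRNAs, adjusted over 16 lists. With the correlation estimated per list, camera called 0 lists in every comparison, and 1 or 2 lists in each had an unadjusted p under 0.05. For the X-linked and Sfmbt2 clusters the estimates were -0.00182 and -0.000986, under the preset value. A higher correlation between members is thus not why the X-linked and Sfmbt2 lists lost their calls. The other lists that camera called had estimates above the preset value. They ran from 0.0302 (miR-99, miR-100 and miR-125) to 0.823 (miR-15 with miR-16), with 0.265 for miR-17~92 and 0.729 for miR-34. For those lists correlation between members may be part of why the calls were lost. fry, which asks whether a list moves one way on balance and compares it with no other list, called 10 in c-Src against mock and 12 in Csk+c-Src against c-Src. Gene neighbours came from an annotation of assembly GRCm38.p6, in which 175 of the 243 tested microRNAs matched 1 gene.

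The steps were tested on simulated data for c-Src against mock, with 60 of 243 microRNAs changed in each of 20 runs. The fit recovered 56.8% of those changed 1.3-fold, 74% at 1.5-fold and 88% at 2-fold. Of its calls 19.8% were false, because scaling moved the unchanged microRNAs together (SD of their median 0.0788 in log2); with median scaling 9.68% were false and with no scaling needed 7.08%. Small differences near that size are the least certain. The simulated changes had random signs, were at most 2-fold and lay in c-Src cells only. In the data limma called from 83 (Csk+c-Src against mock) to 148 (Csk+c-Src against Csk) of 243, in several groups. The share of false calls in the data may therefore differ from the simulated one. A list shifted by 0.5 was found in 50 of 50 runs, and 2 of 700 unshifted lists were called, in data simulated without correlation between members.

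The alternatives changed the background (normexp on raw signal), the scaling (a percentile over all mouse microRNAs, quantile normalization, the authors' total gene signal, the authors' unscaled series table), the summary of probes, the detection filter, the floor, the arrays in the fit, the variance model, a block for the replicate number, and each array left out in turn. Median scaling, an unrounded signal column, normexp without an offset, leaving out the microRNAs at the floor on all arrays and a split of the c-Src arrays were added after the data were seen. A block for the slide was not run, since there is 1 slide. Viral probes were left out of the comparisons.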

Results

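MicroRNA levels were measured on arrays in mouse embryonic fibroblasts that lack Csk, a kinase that phosphorylates and restrains the Src family kinases. The cells had received an empty vector (mock), c-Src, Csk together with c-Src, or Csk alone, with 2 arrays per group and 8 arrays in all. Each array detected between 201 and 250 of 611 mouse microRNAs, and the 243 microRNAs detected on both arrays of at least 1 group were tested. The number of arrays limits the precision of every value. miR-21 held between 10.7% and 17.5% of the summed signal of an array, and the 10 brightest microRNAs held between 49.7% and 52.2%. Across the 243 microRNAs, which are not independent replicates, arrays of the same group correlated at r = 0.9958 to 0.9985 and arrays of different groups at r = 0.9356 to 0.9896. Csk array 2 had 696 excluded spots, against 270 to 351 on the other arrays, and the fewest detected microRNAs (201). The scaling rests on the microRNAs detected on all arrays, so this array bears on every comparison. Without it the median log2 difference over all microRNAs in Csk+c-Src against mock went from -0.0773 to 0.0192. That of the interaction went from 0.169 to 0. The arrays carry no probes for the transfected Csk and c-Src, so the labels could not be checked by the transgenes. The arrays lay on 1 slide with each group in its own column, so an effect of the column cannot be told from an effect of the genes, for any microRNA named below. Standard errors and p-values rest on the spread between arrays of a group. Whether that spread covers differences between separate transfections is not known, so differences between the cell populations apart from Csk and c-Src stay possible throughout. Levels are log2 of the scaled signal with their SD over n = 2 arrays, differences are log2 differences with their standard error from limma, and adjusted p-values are Benjamini-Hochberg values over the 243 microRNAs.

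The first comparison asked which microRNAs change when c-Src is added to cells without Csk. The clearest group was the X-linked cluster that holds miR-322, miR-503, miR-351, miR-542 and miR-450: all 9 tested members fell. After normexp background correction 5 of the 9 fell past the threshold (median -0.825). miR-503 went from -0.78 ± 0.14 in mock cells to -3.29 ± 0.02 in c-Src cells, a log2 difference of -2.50 (SE 0.10, adjusted p = 5.75e-05). miR-322, the brightest member, fell by 1.75 (SE 0.09, adjusted p = 0.000114), miR-351 fell by 1.81 (adjusted p = 0.000114), and miR-322* fell by 2.08 (SE 0.03, adjusted p = 3.57e-06) to -5.61, close to the floor of -5.69. miR-450b-5p fell by 1.52 (SE 0.20, adjusted p = 0.00278), with detection on 1 of the 2 c-Src arrays, miR-450b-3p fell by 1.3 (adjusted p = 0.000398) and miR-450a-5p fell by 1.13 (adjusted p = 6.19e-05). Outside the cluster, miR-455 fell by 1.40 (adjusted p = 4.63e-05), miR-23b fell by 1.18 (adjusted p = 6.19e-05), miR-27b fell by 1.18 (SE 0.06, adjusted p = 8.51e-05) and miR-99a fell by 0.96 (SE 0.04, adjusted p = 5.75e-05). miR-542-3p fell by 0.998 (SE 0.08, adjusted p = 0.000537).

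Among the microRNAs that rose with c-Src, miR-146a went from -4.08 ± 0.12 to -2.36 ± 0.06, 3.31-fold (log2 difference 1.73, SE 0.07, adjusted p = 5.75e-05), and its relative miR-146b rose by 1.32 (adjusted p = 4.63e-05). The neighbouring genes of miR-221 and miR-222 rose together, by 1.5 (SE 0.05, adjusted p = 4.63e-05) and 1.60 (SE 0.09, adjusted p = 0.000137). miR-34c rose by 1.42 (adjusted p = 0.000134) and miR-34b-5p by 1.34 (adjusted p = 0.000372), from levels of -5.01 and -4.69 that lie near the floor. miR-29b rose by 1.09 (adjusted p = 0.000248), miR-29b* by 0.98 (adjusted p = 0.0011) and miR-210, which is known to respond to low oxygen, by 1.02 (SE 0.07, adjusted p = 0.000344). miR-721 was not detected in mock cells and was at least 2.1-fold higher with c-Src (adjusted p = 0.000372). miR-31 rose by 0.66 (adjusted p = 0.000453). miR-21 rose by 0.54 (SE 0.11, adjusted p = 0.0158), a call that ended without mock array 1 (log2 difference 0.46, adjusted p = 0.0669), mock array 2 (0.60, adjusted p = 0.0789), c-Src array 2 (0.43, adjusted p = 0.119) or Csk+c-Src array 2 (0.52, adjusted p = 0.0706). miR-145 was detected on 0 of the 8 arrays and was not tested. Each direction in these paragraphs was the same under all 6 scalings tried. After normexp background correction 4 of these microRNAs were lower with c-Src and did not pass: miR-34c (-0.26), miR-34b-5p (-0.20), miR-721 (-0.58) and miR-29b* (-0.53).

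In limma's test, 108 of the 243 microRNAs differed between c-Src and mock cells, 63 higher and 45 lower, and 22 of them differed at least 2-fold (9 higher, 13 lower). The scaling decided the balance of directions: a percentile over all mouse microRNAs gave 41 higher and 52 lower, and the authors' unscaled series table gave 126 higher and 23 lower, with a median over all microRNAs of 0.31 in place of 0. Across the 6 scalings, 96 of the 108 kept their sign and 59 kept both sign and call. The count was 56 without mock array 2, 67 without Csk+c-Src array 2, 66 with no detection filter and 28 after normexp background correction.

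**Figure D1:**
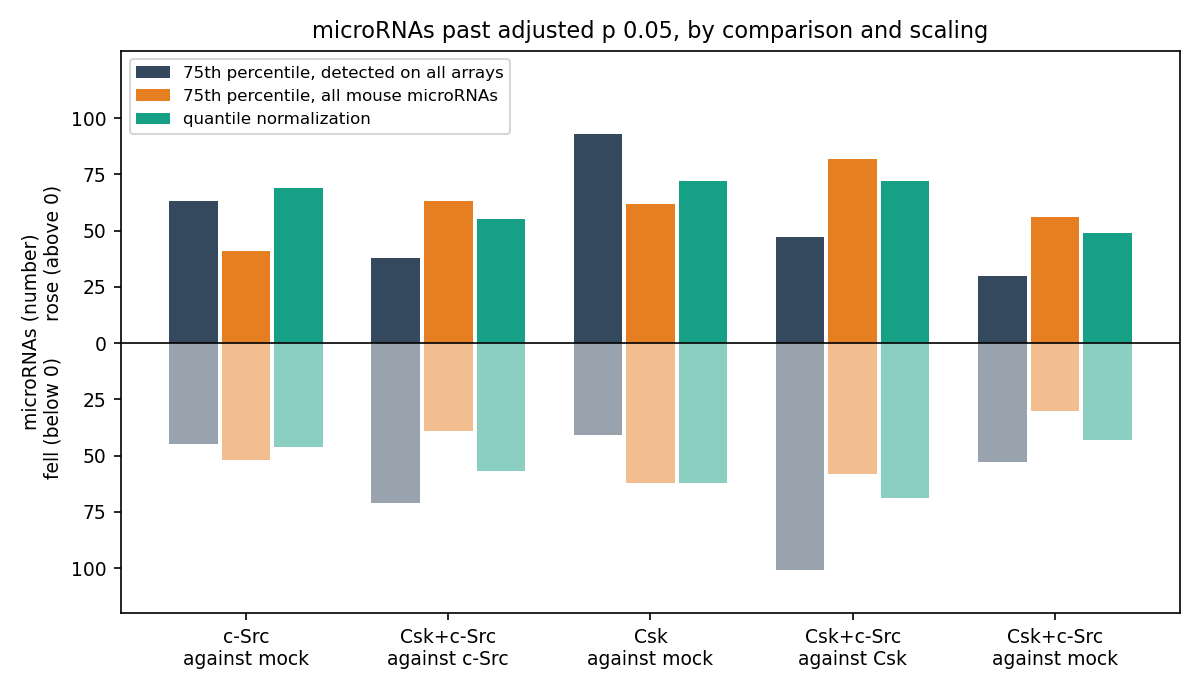
Number of microRNAs past adjusted p = 0.05 that rose (dark bars, above 0) or fell (light bars, below 0) in each of 5 comparisons, under 3 scalings of the arrays. The counts of 63 higher and 45 lower for c-Src against mock became 41 and 52 with a percentile over all mouse microRNAs.

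Of the lists, 16 of 24 had at least 3 tested members and went to camera. In c-Src against mock the X-linked cluster had 0 members that rose and 9 that fell (9 adjusted over the list alone), with a median of -1.52 and a camera adjusted p = 1.28e-06 (adjusted p = 0.0727 with an estimated correlation). In the miR-29 family 5 of 5 rose (5 adjusted over the list alone, median 0.92, camera adjusted p = 0.00185, and adjusted p = 0.383 with an estimated correlation). In the miR-34 family 3 of 3 rose (3 adjusted over the list alone, median 1.34, camera adjusted p = 0.0356, and adjusted p = 0.462 with an estimated correlation). In miR-17~92 and its paralogous clusters, 11 of 15 rose, miR-19b by 0.51 and miR-25 by 0.40 among them, and 0 fell (11 adjusted over the list alone, median 0.32, with 1 member undetected in mock cells). Its camera adjusted p was 0.00185 (adjusted p = 0.453 with an estimated correlation). The list of study microRNAs (miR-99a, miR-27b and miR-542-3p) came from knowledge of publications on these cells and is not independent evidence: 3 of 3 fell (3 adjusted over the list alone, median -0.998, camera adjusted p = 0.00722, and adjusted p = 0.383 with an estimated correlation). These 5 lists kept their direction under all 6 scalings. After normexp camera called 3 of them, the study microRNAs had an adjusted p = 0.0537, and miR-34 had a median of -0.22 and 0 that passed (adjusted p = 0.948).

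The remaining lists did not pass camera in c-Src against mock. The miR-23, miR-27 and miR-24 clusters held 3 that rose and 4 that fell (7 adjusted over the list alone, adjusted p = 0.328), with miR-23a up by 0.40 and the pair miR-23b and miR-27b down. The miR-99, miR-100 and miR-125 clusters held 4 that rose and 2 that fell (6 adjusted over the list alone, adjusted p = 0.657), with miR-125b-5p up by 0.71 and miR-99a down. In let-7, 3 rose, 1 fell and 10 did not pass (4 adjusted over the list alone, adjusted p = 0.836). The Sfmbt2 cluster had 6 that rose and 0 that fell of 15 (6 adjusted over the list alone, adjusted p = 0.113), with miR-466a-3p up by 0.72. In the miR-30 family 0 rose and 2 fell of 9 (2 adjusted over the list alone, adjusted p = 0.328), in miR-181 0 and 2 of 3 (2 adjusted over the list alone, adjusted p = 0.328), and in miR-199 and miR-214 0 and 2 of 5 (2 adjusted over the list alone, adjusted p = 0.38), with miR-199b* at -0.56. The medians of miR-30, of miR-181, and of miR-199 with miR-214 turned from negative to positive in the unscaled table, and the let-7 median from 0.01 to -0.05 with a percentile over all mouse microRNAs. In the miR-15 and miR-16 family 0 of 6 passed (0 adjusted over the list alone, adjusted p = 0.934), miR-16 and miR-15b at 0.05 and 0.00; 6 of 6 rose in the unscaled table, and 1 rose and 2 fell with quantile normalization.

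Marker lists for other cell types were mostly undetected. The miR-200 family (epithelial) had 1 of 9 members detected and 0 tested, and miR-203 and miR-205 (keratinocyte) 0 of 3 detected. The muscle list had 1 tested member, miR-206 (0.03, not passed), the blood cell list miR-486 (-0.14, not passed, 0.17 in the unscaled table), and the endothelial list miR-126-3p, which rose by 0.21 (adjusted p = 0.0411). In the neural list 2 rose and 1 fell of 4 (3 adjusted over the list alone, adjusted p = 0.541), with miR-128 up by 0.31. In the embryonic stem cell clusters 0 of 3 passed (0 adjusted over the list alone, adjusted p = 0.657), among them miR-291b-5p (-0.60) and miR-290-3p (-0.72). In the miR-96, miR-182 and miR-183 cluster 0 of 4 passed (0 adjusted over the list alone, adjusted p = 0.904, miR-96 -0.10, miR-183 -0.07), and miR-183 was higher by 0.24 in the unscaled table (adjusted p = 0.04). The Dlk1-Dio3 cluster had 3 of 71 members detected and 0 of 2 tested passed (miR-494 -0.04, miR-487b -0.21). miR-221 and miR-222 had 2 of 2 that rose (2 adjusted over the list alone), and the miR-143 and miR-145 list had its 1 tested member, miR-143, fall by 0.66 (1 adjusted over the list alone). Lists with fewer than 3 tested members were not tested with camera.

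Several small differences in c-Src against mock lost their call when an array was left out. Of the named calls in this comparison 17 ended in this way, 15 of them in each of 2 to 7 separate fits, so most did not depend on 1 array alone. In 68 of the 76 fits that ended a call the log2 difference moved by less than its SE, and in 71 the SE grew. Given here is the fit with the highest adjusted p. Without mock array 2 the log2 difference of miR-23a went from 0.40 (SE 0.06) to 0.42 (SE 0.10, adjusted p = 0.0549), of miR-100 from -0.15 (SE 0.03) to -0.16 (SE 0.06, adjusted p = 0.12), of miR-30a from -0.16 (SE 0.04) to -0.15 (SE 0.07, adjusted p = 0.182) and of miR-30d from -0.25 (SE 0.06) to -0.29 (SE 0.10, adjusted p = 0.122). Without the same array miR-181a went from -0.28 (SE 0.07) to -0.29 (SE 0.12, adjusted p = 0.177), miR-199a-3p from -0.27 (SE 0.07) to -0.24 (SE 0.12, adjusted p = 0.221), miR-219 from -0.26 (SE 0.06) to -0.25 (SE 0.09, adjusted p = 0.13) and miR-126-3p from 0.21 (SE 0.06) to 0.12 (SE 0.09, adjusted p = 0.352). let-7c-1* (adjusted p = 0.166 without it) was not detected in c-Src cells and lay at least 1.64-fold lower there. Without c-Src array 2 let-7i went from 0.48 (SE 0.09) to 0.41 (SE 0.12, adjusted p = 0.0893), let-7d from 0.30 (SE 0.07) to 0.23 (SE 0.09, adjusted p = 0.136), miR-24-2* from 0.31 (SE 0.08) to 0.24 (SE 0.12, adjusted p = 0.219) and miR-669f from 0.42 (SE 0.08) to 0.37 (SE 0.12, adjusted p = 0.108). Without c-Src array 1 miR-181b went from -0.30 (SE 0.06) to -0.29 (SE 0.07, adjusted p = 0.0512), and without Csk array 2 miR-99b* stayed at 0.27 (SE 0.07, then 0.11, adjusted p = 0.13), while miR-9 (at least 1.1-fold higher) had an adjusted p of 0.329. The signs of miR-100, miR-30a, miR-30d, miR-181a, miR-181b, miR-199a-3p and miR-219 turned positive in the unscaled table, and those of miR-126-3p, miR-24-2*, miR-669f, miR-99b*, miR-9, miR-128 and miR-466a-3p turned negative after normexp. With the mean of log2 over probes miR-99b* was at -0.012 and miR-100 at 0.0475, and with quantile normalization miR-15b fell by 0.29 (adjusted p = 0.00393).

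The next comparison asked what Csk does to cells that carry c-Src. The X-linked cluster went back up, with 9 of 9 tested members higher: miR-503 rose by 2.04 (SE 0.10, adjusted p = 8.42e-05), miR-322* by 1.97 (SE 0.03, adjusted p = 4.7e-06), miR-322 by 1.5 (adjusted p = 0.000156), miR-351 by 1.38 (adjusted p = 0.000231) and miR-450b-5p by 1.09 (adjusted p = 0.00777). Only 2 of the 9 rose past the threshold after normexp (median 0.315). miR-99a rose by 1.23 (SE 0.04, adjusted p = 3.56e-05), miR-27b by 0.998 (SE 0.06, adjusted p = 0.000109) and miR-542-3p by 0.56 (SE 0.08, adjusted p = 0.00382). miR-455 rose by 1.26 (adjusted p = 4.53e-05), miR-218 by 1.23 (adjusted p = 3.97e-05) and miR-574-3p by 1.05 (adjusted p = 0.000385). let-7c-1* was at least 2.21-fold higher (adjusted p = 0.00607, and 0.0548 without c-Src array 2).

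The largest falls with Csk in c-Src cells included miR-10a, which did not pass in c-Src against mock. Others, such as miR-146a, miR-222 and miR-221, were microRNAs that c-Src alone had raised. miR-146a, at -2.36 ± 0.06 in c-Src cells, was not detected on either Csk+c-Src array and was at least 10.1-fold lower there (adjusted p = 5.84e-06). miR-10a and miR-196a, whose genes lie in Hox clusters, changed by -2.29 (SE 0.09, adjusted p = 4.53e-05) and -1.49 (SE 0.11, adjusted p = 0.000282). miR-222 and miR-221 fell by 1.68 (adjusted p = 0.000107) and fell by 1.36 (adjusted p = 4.53e-05), miR-338-3p fell by 1.63 (adjusted p = 8.42e-05), miR-34b-5p fell by 1.28 (adjusted p = 0.000341), miR-34c fell by 1.26 (adjusted p = 0.000174) and miR-193b fell by 1.11 (adjusted p = 7.41e-05). miR-721 was at least 2.1-fold lower (adjusted p = 0.000292), and 0.00309 after normexp. miR-31 fell by 0.80 (adjusted p = 0.000216) and miR-210 fell by 0.69 (adjusted p = 0.00112). miR-21 was lower by a log2 difference of -0.29 and did not pass (adjusted p = 0.0943).

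In limma's test, 109 microRNAs differed between Csk+c-Src and c-Src cells, 38 higher and 71 lower, and 23 at least 2-fold (10 higher, 13 lower). With a percentile over all mouse microRNAs the split was 63 higher and 39 lower, with quantile normalization 55 and 57, and 26 and 91 with the unscaled table; the median over all microRNAs was -0.08, and 0.11 and -0.23 under the first and last of these. Across the 6 scalings 102 kept their sign and 64 kept sign and call. Without Csk array 2 the split was 56 higher and 49 lower, and after normexp 19 microRNAs were called.

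**Figure D2:**
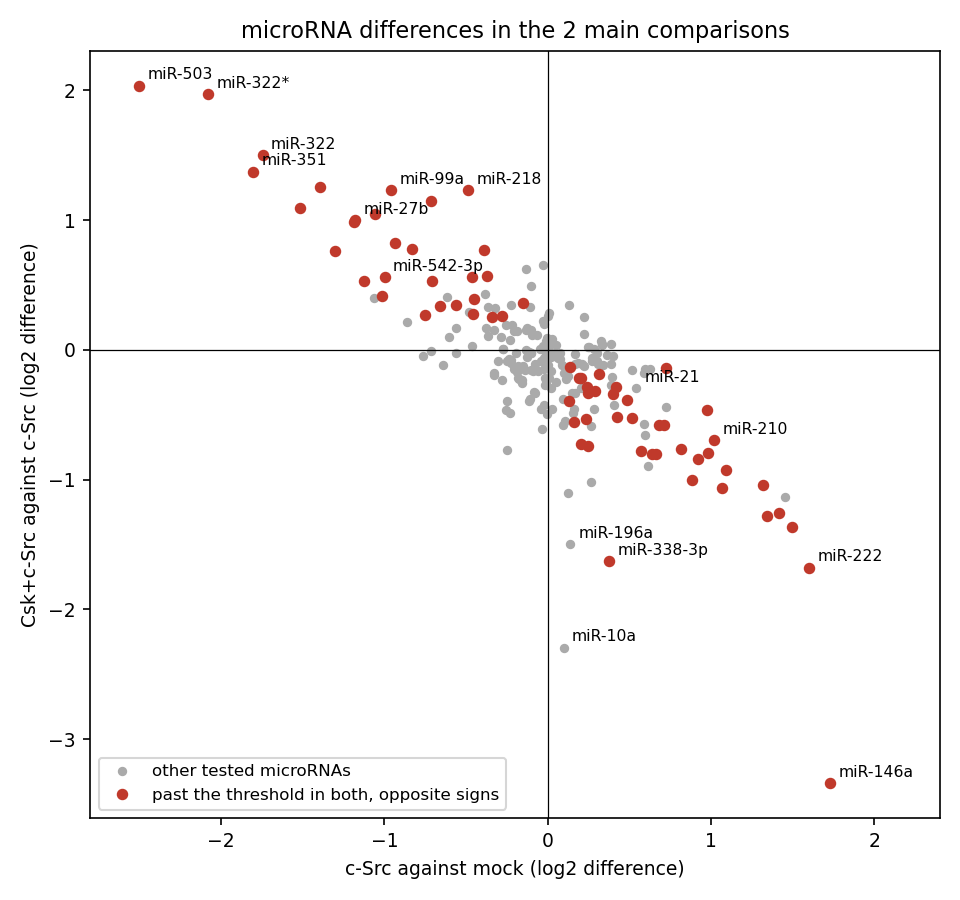
Log2 difference of each of the 243 tested microRNAs in c-Src against mock (horizontal) and in Csk+c-Src against c-Src (vertical), with the 68 that passed in both with opposite signs in red. miR-503 sits at -2.50 and 2.04, and miR-10a at 0.10 and -2.29.

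By camera, the X-linked cluster shifted up (9 rose, 0 fell, 9 adjusted over the list alone, median 1.09, adjusted p = 9.47e-07, and adjusted p = 0.0699 with an estimated correlation). The miR-23, miR-27 and miR-24 clusters shifted up, with 4 that rose, miR-23b by 0.99 among them, and 0 that fell (4 adjusted over the list alone, median 0.25, adjusted p = 0.0141, and adjusted p = 0.719 with an estimated correlation). The miR-29 family shifted down, with 0 that rose and 5 that fell, miR-29a* by -1.01 and miR-29b by -0.92 (5 adjusted over the list alone, median -0.84, adjusted p = 0.0141, and adjusted p = 0.423 with an estimated correlation). The Sfmbt2 cluster shifted down, with 0 that rose and 9 that fell of 15, miR-467b by -0.55 and miR-669a by -0.54 (10 adjusted over the list alone, median -0.27, with 1 member undetected in Csk+c-Src cells). Its camera adjusted p was 0.0141 (adjusted p = 0.295 with an estimated correlation). The study microRNAs, not independent evidence, had 3 of 3 that rose (3 adjusted over the list alone, median 0.998, adjusted p = 0.00642, and adjusted p = 0.358 with an estimated correlation). These 5 lists kept their direction under all 6 scalings. After normexp 4 of them passed camera, and the Sfmbt2 median was 0 (adjusted p = 0.994).

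The other lists did not pass camera in this comparison. In the miR-34 family 0 rose and 2 fell of 3 (3 adjusted over the list alone, adjusted p = 0.13). In miR-17~92 0 rose and 3 fell of 15 (3 adjusted over the list alone, adjusted p = 0.939), with miR-25 at -0.34, and 5 rose with 0 that fell under a percentile over all mouse microRNAs. let-7 had 1 that rose and 2 that fell (3 adjusted over the list alone, adjusted p = 0.757). The miR-99, miR-100 and miR-125 clusters had 2 and 2 (4 adjusted over the list alone, adjusted p = 0.757), with miR-100 at 0.36 and miR-125b-5p at -0.58. miR-15 and miR-16 had 0 and 3, miR-497 at -0.61 and miR-195 at -0.54 (3 adjusted over the list alone, adjusted p = 0.289), and miR-30 had 0 and 3, miR-30c at -0.50 and miR-30e at -0.39 (3 adjusted over the list alone, adjusted p = 0.625). miR-181 had 0 and 1 (1 adjusted over the list alone, adjusted p = 0.782), miR-199 and miR-214 had 1 and 3, miR-199b* at 0.35 and miR-199a-5p at -0.42 (4 adjusted over the list alone, adjusted p = 0.757), and the neural list 0 and 2 (4 adjusted over the list alone, adjusted p = 0.757). The embryonic stem cell clusters had 0 and 1 (1 adjusted over the list alone, adjusted p = 0.939) and the miR-96, miR-182 and miR-183 cluster 0 and 0 (0 adjusted over the list alone, adjusted p = 0.757). The medians of let-7, the miR-99, miR-100 and miR-125 clusters, the miR-15 and miR-16 family, the miR-30 family, the neural list and the embryonic stem cell clusters turned from negative to positive with a percentile over all mouse microRNAs. Of the lists with fewer than 3 tested members, miR-221 and miR-222 had 2 that fell, miR-143 rose by 0.34, miR-126-3p (endothelial) fell by 0.73 and miR-206 (muscle) fell by 0.46, while miR-486 (blood, 0.15) and 2 Dlk1-Dio3 members (miR-494 -0.08, miR-487b 0.15) did not pass.

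Calls of small differences ended here too when an array was left out: 10 named calls, 9 of them in each of 2 to 7 separate fits. In 32 of the 43 fits that ended a call the log2 difference moved by less than its SE, and in 35 the SE grew. Without Csk+c-Src array 2 let-7g went from -0.28 (SE 0.07) to -0.26 (SE 0.11, adjusted p = 0.184), miR-106b from -0.32 (SE 0.06) to -0.27 (SE 0.11, adjusted p = 0.172) and miR-181a from -0.24 (SE 0.07) to -0.17 (SE 0.12, adjusted p = 0.413). Without c-Src array 2 let-7i went from -0.38 (SE 0.09) to -0.30 (SE 0.12, adjusted p = 0.154), and without c-Src array 1 miR-214* from -0.45 (SE 0.09) to -0.42 (SE 0.12, adjusted p = 0.0592). Without Csk array 2 the difference itself shrank for miR-125a-3p, from -0.33 (SE 0.06) to -0.18 (SE 0.08, adjusted p = 0.152), and for miR-128, from -0.19 (SE 0.05) to -0.04 (SE 0.03, adjusted p = 0.463). Without that array the calls of miR-290-5p (at least 1.5-fold lower, adjusted p = 0.148) and miR-9 (at least 1.1-fold lower, adjusted p = 0.337) ended as well. Csk array 2 is in neither group of this comparison, so leaving it out moved the log2 differences only through the scaling and the floor. The median over all microRNAs then went from -0.0832 to 0.0106. miR-128 was positive, at 0.05, with a percentile over all mouse microRNAs, and after normexp miR-128, miR-125a-3p, miR-214* and miR-290-5p were all above 0 and not passed.

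Of the 108 microRNAs that differed between c-Src and mock cells, 68 (63%) turned back with Csk: 30 that c-Src lowered rose and 38 that it raised fell, while 5 went the same way again. The X-linked members, miR-99a, miR-27b, miR-221 and miR-222 were among the 68. In Csk+c-Src cells 43 of the 68 no longer differed from mock cells past the threshold, which does not show them to be equal; 14 stayed on the c-Src side of mock and 11 went past mock. Both comparisons share the c-Src arrays, and 100 simulated draws with no effect gave a mean of 0.01 and at most 1 such microRNA. Draws with no effect give few calls, so that count cannot show how many of the 68 come from sharing the arrays. Independent lists of these sizes would share 25.4. The covariance of the differences was -0.264, against -0.00744 in the simulation (a difference of -0.256), and r was -0.801 (-0.485 in the simulation), across microRNAs that are not independent replicates. With the c-Src arrays split, 1 for each comparison and the spread pooled over all groups, 52 and 54 turned back in the 2 ways to split them, with r of -0.789 and -0.728 and covariances of -0.261 and -0.25. The split leaves in place any error common to both c-Src arrays. The count was 42 without mock array 2 and 14 after normexp.

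**Figure D3:**
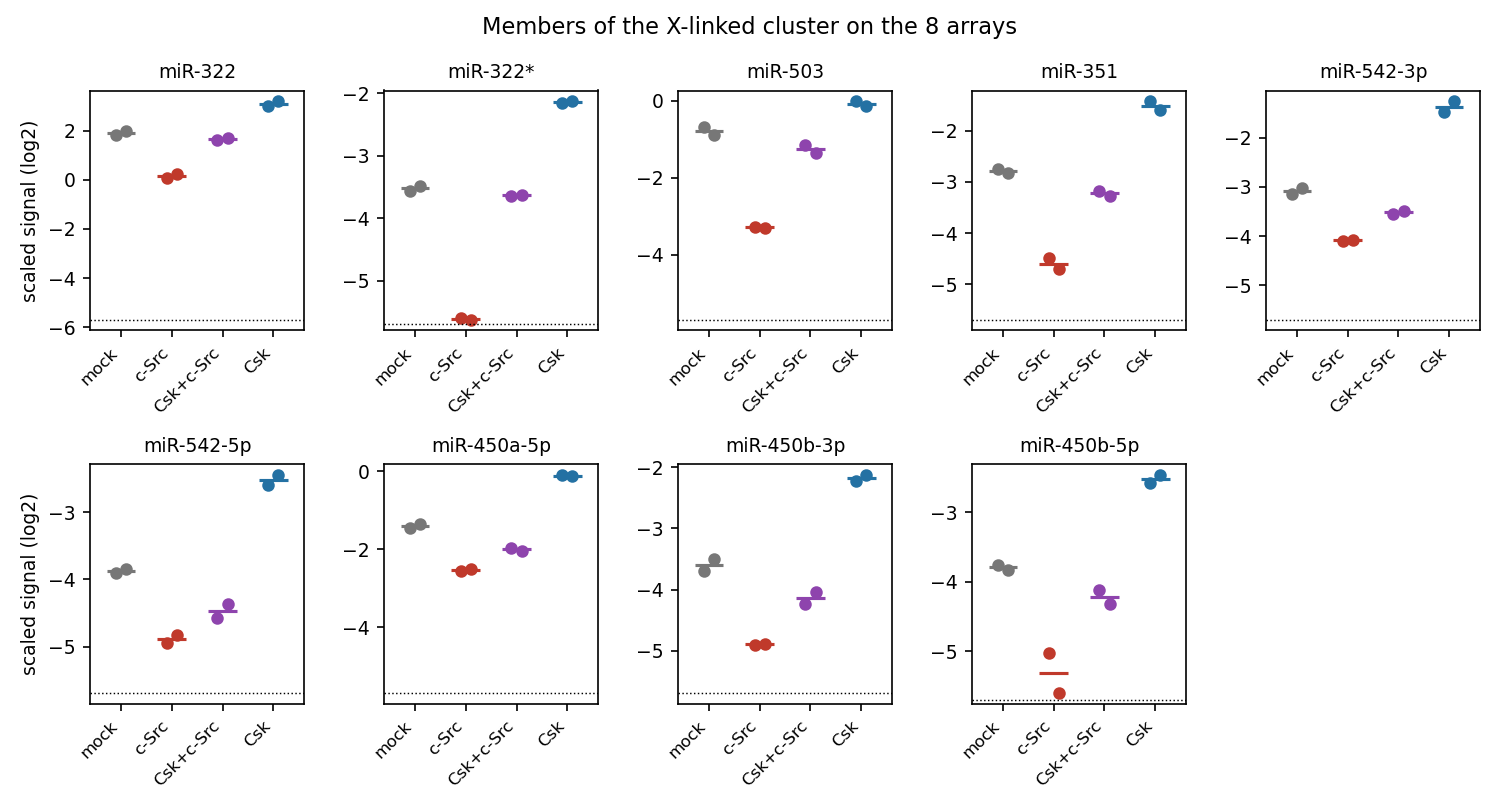
Scaled signal (log2) of the 9 tested members of the X-linked cluster on each array (points) with the group mean (lines); the dotted line is the floor at -5.69. miR-322 averages 1.91 in mock, 0.16 in c-Src, 1.67 in Csk+c-Src and 3.1 in Csk cells.

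The comparison of Csk with mock cells asked what Csk alone does where no c-Src was added. miR-542-3p, of the X-linked cluster, rose by 1.71 (SE 0.08, adjusted p = 7.03e-05), and all 9 tested members rose, of which 2 passed after normexp (median 0.14). miR-721 and miR-135a*, not detected in mock cells, were at least 3.69-fold (adjusted p = 5.24e-05) and at least 3.67-fold (adjusted p = 0.000236) higher, and after normexp at -0.26 and -0.27, neither passed. miR-143, usually high in smooth muscle and fibroblasts, fell by 2.51 from -2.54 ± 0.01 to -5.05 ± 0.01 (SE 0.05, adjusted p = 4.39e-06), with detection on 1 of the 2 Csk arrays. In the Sfmbt2 cluster, miR-669f fell by 1.81 (SE 0.08, adjusted p = 7.03e-05), and miR-467b was not detected in Csk cells, at least 3.77-fold lower (adjusted p = 1.73e-06). limma called 134 microRNAs, 93 higher and 41 lower, 25 at least 2-fold (15 higher, 10 lower). The split was 62 and 62 with a percentile over all mouse microRNAs, 72 and 62 with quantile normalization and 80 and 59 with median scaling, and 125 of the 134 kept their sign and 85 sign and call. After normexp 19 were called.

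Camera called 6 lists in Csk against mock, and 0 of them with an estimated correlation, where the lowest adjusted p was 0.0914. The X-linked cluster (9 rose, 0 fell, 9 adjusted over the list alone, camera adjusted p = 0.000878, and adjusted p = 0.121 with an estimated correlation) and the Sfmbt2 cluster (0 rose, 9 fell of 15, 9 adjusted over the list alone, camera adjusted p = 1.26e-05, and adjusted p = 0.0914 with an estimated correlation) led them. Of the 15 Sfmbt2 members 13 were detected in mock cells and not in Csk cells, so the size of its median (-0.47) depends on the floor. The miR-15 and miR-16 family had 6 of 6 that rose (6 adjusted over the list alone, adjusted p = 0.0433, and adjusted p = 0.562 with an estimated correlation) and the miR-30 family 7 of 9 (7 adjusted over the list alone, adjusted p = 0.0477, and adjusted p = 0.459 with an estimated correlation). In the former 3 rose and 1 fell with quantile normalization, where miR-15b was at -0.18 and miR-16 at -0.15, and 3 rose with a percentile over all mouse microRNAs. In miR-30 that percentile gave 5 that rose and 1 that fell. The miR-29 family had 3 of 5 that fell (3 adjusted over the list alone, adjusted p = 0.0422, and adjusted p = 0.459 with an estimated correlation), and the study microRNAs, not independent evidence, 3 of 3 that rose (3 adjusted over the list alone, adjusted p = 0.0433, and adjusted p = 0.459 with an estimated correlation). After normexp miR-29 (adjusted p = 0.0697) and miR-30 (median -0.0375, adjusted p = 0.0886) did not pass, and let-7 (adjusted p = 0.0467) and the miR-23, miR-27 and miR-24 clusters (adjusted p = 0.0104) did.

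The other 10 lists did not pass camera in Csk against mock. miR-17~92 held 4 that rose and 0 that fell of 15 (3 adjusted over the list alone, adjusted p = 0.957). let-7 had 6 that rose and 0 that fell of 14 (6 adjusted over the list alone, adjusted p = 0.381). The miR-99, miR-100 and miR-125 clusters held 4 that rose and 0 that fell of 7 (4 adjusted over the list alone, adjusted p = 0.218). The miR-23, miR-27 and miR-24 clusters had 4 that rose and 0 that fell of 7 (4 adjusted over the list alone, adjusted p = 0.162). miR-34 held 1 that rose and 2 that fell of 3 (3 adjusted over the list alone, adjusted p = 0.37). miR-181 had 0 that rose and 2 that fell of 3 (2 adjusted over the list alone, adjusted p = 0.173). miR-199 with miR-214 held 3 that rose and 2 that fell of 5 (5 adjusted over the list alone, adjusted p = 0.957). The neural list had 2 that rose and 1 that fell of 4 (3 adjusted over the list alone, adjusted p = 0.963). The embryonic stem cell clusters held 1 that rose and 0 that fell of 3 (1 adjusted over the list alone, adjusted p = 0.752). The miR-96, miR-182 and miR-183 cluster had 3 that rose and 0 that fell of 4 (3 adjusted over the list alone, adjusted p = 0.218). The let-7 median turned from 0.30 to -0.00588 with quantile normalization. Of the lists with fewer than 3 tested members, miR-221 and miR-222 had 2 that fell, and 0 of 2 Dlk1-Dio3 members passed. The only tested members of 3 marker lists for other cell types, named after their values were seen, all passed: miR-206 (muscle) fell by 0.67 (adjusted p = 0.000397), miR-486 (blood cells) fell by 0.37 (adjusted p = 0.0237) and miR-126-3p (endothelial) rose by 0.57 (adjusted p = 0.000789). The call of miR-486 ended in 5 fits that left out an array, with the highest adjusted p, 0.143, without mock array 2 (log2 difference from -0.37, SE 0.10, to -0.25, SE 0.11), and it was at 0.02 with quantile normalization. After normexp none of the markers passed, and miR-126-3p was at -0.24.

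The comparison of Csk+c-Src with Csk cells asked what c-Src does where Csk is present. The X-linked cluster fell again (0 rose, 9 fell, and 4 fell after normexp, median -0.696), with miR-542-3p down by a log2 difference of -2.14 (SE 0.08, adjusted p = 3.06e-05). miR-143 rose by 2.19 (SE 0.05, adjusted p = 6.63e-06), miR-10b by 2.04 (SE 0.06, adjusted p = 9.8e-06) and miR-669f by 1.94 (SE 0.08, adjusted p = 3.1e-05). miR-10a fell by 2.93 (SE 0.09, adjusted p = 1.23e-05), and miR-146a was at least 6.16-fold lower (adjusted p = 6.64e-06). limma called 148 microRNAs, 47 higher and 101 lower, 36 at least 2-fold (13 higher, 23 lower). With a percentile over all mouse microRNAs the split was 82 higher and 58 lower with a median over all of 0.11 in place of -0.15, with quantile normalization 72 and 69, with median scaling 64 and 79, and 64 and 78 with the unscaled table; without Csk array 2 it was 64 and 66. Across scalings 125 kept their sign and 103 sign and call, and after normexp 39 were called.

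Camera called 6 lists in Csk+c-Src against Csk, and 0 with an estimated correlation, where the lowest adjusted p was 0.131. Those down were the X-linked cluster (9 adjusted over the list alone, adjusted p = 0.00127, and adjusted p = 0.131 with an estimated correlation), miR-15 and miR-16 (0 rose, 6 fell, 6 adjusted over the list alone, adjusted p = 0.0304, and adjusted p = 0.617 with an estimated correlation) and miR-30 (0 rose, 8 fell, 9 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.511 with an estimated correlation). Those up were the Sfmbt2 cluster (7 rose, 0 fell, 6 adjusted over the list alone, adjusted p = 0.000313, and adjusted p = 0.131 with an estimated correlation), miR-29 (4 rose, 0 fell, 4 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.511 with an estimated correlation) and miR-17~92 (8 rose, 2 fell, 12 adjusted over the list alone, adjusted p = 0.0181, and adjusted p = 0.617 with an estimated correlation). Of the 15 Sfmbt2 members 12 were detected in Csk+c-Src cells and not in Csk cells, so the size of its median (0.10) depends on the floor. With a percentile over all mouse microRNAs 3 of the miR-15 and miR-16 family and 6 of miR-30 fell, and with quantile normalization 3 of the former, where miR-15b was at 0.06 and miR-16 at 0.00. These lists kept the sign of their median under all 6 scalings. After normexp the Sfmbt2 median was 0 (adjusted p = 0.0571), and the study microRNAs passed (adjusted p = 0.00643). The log2 difference of miR-15b went from -0.47 (SE 0.08) to -0.22 (SE 0.07, adjusted p = 0.0855) without Csk array 2.

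In Csk+c-Src against Csk 10 lists did not pass camera. let-7 held 0 that rose and 6 that fell of 14 (4 adjusted over the list alone, adjusted p = 0.766). The miR-99, miR-100 and miR-125 clusters had 0 that rose and 3 that fell of 7 (3 adjusted over the list alone, adjusted p = 0.766). The miR-23, miR-27 and miR-24 clusters held 2 that rose and 4 that fell of 7 (6 adjusted over the list alone, adjusted p = 0.766). miR-34 had 2 that rose and 1 that fell of 3 (3 adjusted over the list alone, adjusted p = 0.317). miR-181 held 0 that rose and 0 that fell of 3 (0 adjusted over the list alone, adjusted p = 0.805). miR-199 with miR-214 had 1 that rose and 3 that fell of 5 (4 adjusted over the list alone, adjusted p = 0.766). The neural list held 1 that rose and 2 that fell of 4 (3 adjusted over the list alone, adjusted p = 0.805). The embryonic stem cell clusters had 0 that rose and 1 that fell of 3 (1 adjusted over the list alone, adjusted p = 0.805). The miR-96, miR-182 and miR-183 cluster held 0 that rose and 4 that fell of 4 (4 adjusted over the list alone, adjusted p = 0.382). The study microRNAs (not independent evidence) had 0 that rose and 3 that fell of 3 (3 adjusted over the list alone, adjusted p = 0.0634). The medians of let-7, of the miR-99, miR-100 and miR-125 clusters and of the embryonic stem cell clusters turned positive with a percentile over all mouse microRNAs. miR-221 and miR-222 had 2 that rose, and 0 of 2 Dlk1-Dio3 members passed. Of the same markers, miR-126-3p fell by 1.10 (adjusted p = 6.86e-05), miR-486 rose by 0.39 (adjusted p = 0.019) and miR-206 rose by 0.24 (adjusted p = 0.0164). The call of miR-486 ended in 3 fits that left out an array, with the highest adjusted p, 0.095, without Csk+c-Src array 2 (log2 difference from 0.39, SE 0.10, to 0.37, SE 0.13). That of miR-206 ended in 3 as well, with 0.0996 without Csk+c-Src array 1 (from 0.24, SE 0.06, to 0.20, SE 0.08). After normexp none of the markers passed, and miR-206 was at -0.0415 and miR-486 at -0.0584.

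The comparison of Csk+c-Src with mock cells asked how far the cells with both genes differ from the vector cells. The largest differences were falls: miR-10a from -3.03 ± 0.15 to -5.23 ± 0.09 (log2 difference -2.20, SE 0.09, adjusted p = 0.000236), miR-196a by -1.36 (SE 0.11, adjusted p = 0.00085), and miR-146a at least 3.05-fold lower (adjusted p = 0.000236). miR-218 rose by 0.74 (SE 0.04, adjusted p = 0.000452), miR-140* by 0.62 (adjusted p = 0.00152) and miR-466a-3p by 0.58 (adjusted p = 0.000763), while after normexp miR-218 was at -0.0115 and miR-466a-3p at -0.44. limma called 83 microRNAs, 30 higher and 53 lower, 5 at least 2-fold (0 higher, 5 lower), and 56 higher with 30 lower under a percentile over all mouse microRNAs, 49 and 43 with quantile normalization, 46 and 54 with median scaling, 50 and 18 in the unscaled table and 56 and 32 without Csk array 2. Across scalings 81 kept their sign and 41 sign and call. The count was 30 without Csk+c-Src array 2, 32 without mock array 2, 53 without Csk+c-Src array 1, 46 with no detection filter and 1 after normexp. Camera called 3 lists and 0 with an estimated correlation: miR-17~92 (7 rose, 0 fell, 8 adjusted over the list alone, adjusted p = 0.000404, and adjusted p = 0.518 with an estimated correlation), the miR-99, miR-100 and miR-125 clusters (2 rose, 0 fell, 2 adjusted over the list alone, adjusted p = 0.0319, and adjusted p = 0.465 with an estimated correlation) and the X-linked cluster (0 rose, 6 fell, 8 adjusted over the list alone, adjusted p = 0.0315, and adjusted p = 0.465 with an estimated correlation), of which 2 fell with a percentile over all mouse microRNAs and 2 in the unscaled table. After normexp the X-linked cluster did not pass (adjusted p = 0.143), and let-7 (adjusted p = 0.0391) and the miR-23, miR-27 and miR-24 clusters (adjusted p = 0.0433) did. In both of the latter lists 0 members rose and 0 fell past the threshold. Their medians were 0.0248 and -0.091, while the median over all microRNAs was -0.457, and camera compares a list with the other microRNAs.

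In Csk+c-Src against mock 13 lists did not pass camera. let-7 held 1 that rose and 0 that fell of 14 (0 adjusted over the list alone, adjusted p = 0.28). The miR-23, miR-27 and miR-24 clusters had 2 that rose and 1 that fell of 7 (4 adjusted over the list alone, adjusted p = 0.647). The miR-15 and miR-16 family held 0 that rose and 3 that fell of 6 (4 adjusted over the list alone, adjusted p = 0.195). miR-29 had 0 that rose and 0 that fell of 5 (0 adjusted over the list alone, adjusted p = 0.249). miR-30 held 0 that rose and 4 that fell of 9 (4 adjusted over the list alone, adjusted p = 0.148). miR-34 had 0 that rose and 0 that fell of 3 (0 adjusted over the list alone, adjusted p = 0.28). miR-181 held 0 that rose and 2 that fell of 3 (2 adjusted over the list alone, adjusted p = 0.285). miR-199 with miR-214 had 0 that rose and 4 that fell of 5 (5 adjusted over the list alone, adjusted p = 0.0858). The neural list held 0 that rose and 0 that fell of 4 (0 adjusted over the list alone, adjusted p = 0.647). The embryonic stem cell clusters had 0 that rose and 0 that fell of 3 (0 adjusted over the list alone, adjusted p = 0.398). The miR-96, miR-182 and miR-183 cluster held 0 that rose and 0 that fell of 4 (0 adjusted over the list alone, adjusted p = 0.647). The Sfmbt2 cluster had 1 that rose and 7 that fell of 15 (8 adjusted over the list alone, adjusted p = 0.28). The study microRNAs (not independent evidence) held 1 that rose and 1 that fell of 3 (3 adjusted over the list alone, adjusted p = 0.994). The medians of the miR-23, miR-27 and miR-24 clusters, the neural list and the miR-96, miR-182 and miR-183 cluster turned positive with a percentile over all mouse microRNAs, and that of the study microRNAs in the unscaled table. miR-221 and miR-222 had 0 that passed, miR-143 fell by 0.32, and 0 of 2 Dlk1-Dio3 members passed. Of the markers, miR-206 fell by 0.43 (adjusted p = 0.00519), miR-126-3p fell by 0.52 (adjusted p = 0.00295), and miR-486 was at 0.02 (adjusted p = 0.96). Without Csk+c-Src array 2 miR-206 was at -0.38 (SE from 0.06 to 0.09, adjusted p = 0.0722) and miR-126-3p at -0.51 (SE from 0.06 to 0.11, adjusted p = 0.0569), and without mock array 2 miR-206 was at -0.35 (adjusted p = 0.052). With quantile normalization miR-206 (adjusted p = 0.071) and miR-126-3p (adjusted p = 0.0615) did not pass, and miR-486 did, at 0.33. After normexp none of the markers passed.

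**Figure D4:**
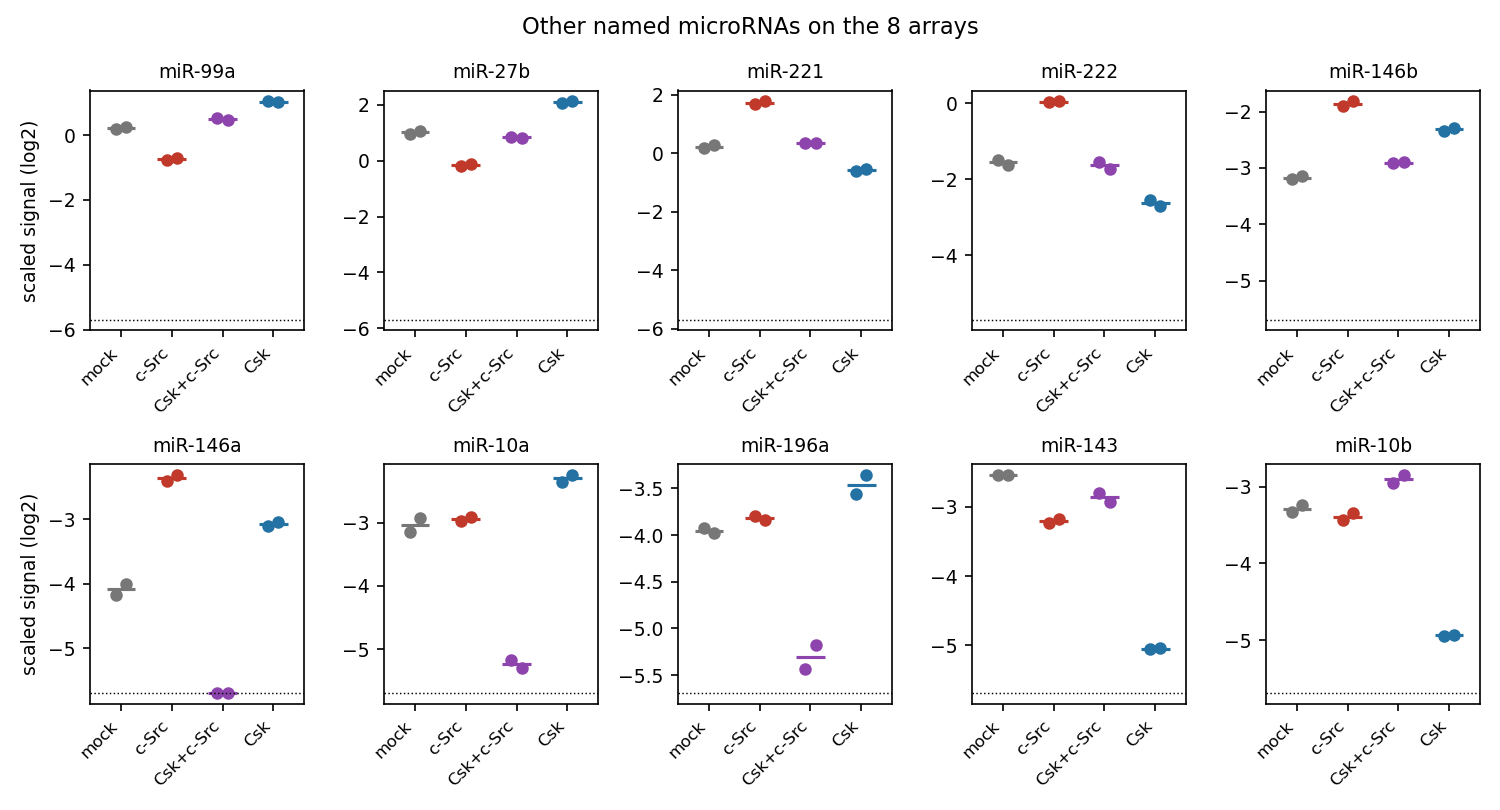
Scaled signal (log2) of 10 named microRNAs on each array (points) with the group mean (lines); the dotted line is the floor at -5.69. miR-10a averages -3.03 in mock, -2.94 in c-Src, -5.23 in Csk+c-Src and -2.30 in Csk cells.

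The test of the interaction asked whether the effect of c-Src differs without and with Csk, as the difference between c-Src against mock and Csk+c-Src against Csk. The difference was positive for miR-10a (3.03, SE 0.13, adjusted p = 5.35e-05), which c-Src left at a log2 difference of 0.10 without Csk (adjusted p = 0.431) and lowered by -2.93 with it. It was negative for miR-143 (-2.85, SE 0.07, adjusted p = 2.03e-05), which fell with c-Src in one setting and rose in the other, for miR-10b (-2.14, SE 0.08, adjusted p = 3.89e-05) and for miR-455 (-2.14, SE 0.07, adjusted p = 2.19e-05). It was positive for miR-146a (adjusted p = 1.77e-05) and miR-721 (adjusted p = 3.89e-05), whose sizes depend on the floor because each was undetected in at least 1 group; miR-721 was at -0.26 after normexp. limma called 123 microRNAs, 90 positive and 33 negative, 34 at least 2-fold (21 positive, 13 negative), and 141 at an unadjusted p under 0.05. Of the 123, 22 were called in opposite directions by the 2 comparisons, 28 in the same direction, 15 only without Csk, 56 only with it and 2 by neither. The split was 34 positive and 69 negative with a percentile over all mouse microRNAs (median over all -0.13, in place of 0.17), 63 and 60 with quantile normalization (median -0.01), and 114 and 31 in the unscaled table (median 0.37); 99 kept their sign and 54 sign and call. Without Csk array 2 the split was 54 and 50, without Csk+c-Src array 2 the count was 80, and after normexp it was 1. Camera called 1 list, the Sfmbt2 cluster (0 positive, 6 negative, 6 adjusted over the list alone, adjusted p = 0.00463, and adjusted p = 0.278 with an estimated correlation), most of whose tested members were not detected in Csk cells. After normexp it did not pass (adjusted p = 0.0798), and the miR-15 and miR-16 family did (adjusted p = 0.0101). c-Src moved 55 microRNAs the same way in both settings, 28 up and 27 down.

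For the interaction 15 lists did not pass camera. miR-17~92 held 4 positive and 0 negative of 15 (4 adjusted over the list alone, adjusted p = 0.889). let-7 had 5 positive and 0 negative of 14 (4 adjusted over the list alone, adjusted p = 0.889). The miR-99, miR-100 and miR-125 clusters held 3 positive and 1 negative of 7 (4 adjusted over the list alone, adjusted p = 0.889). The X-linked cluster had 4 positive and 2 negative of 9 (6 adjusted over the list alone, adjusted p = 0.889). The miR-23, miR-27 and miR-24 clusters held 1 positive and 0 negative of 7 (0 adjusted over the list alone, adjusted p = 0.889). The miR-15 and miR-16 family had 6 positive and 0 negative of 6 (6 adjusted over the list alone, adjusted p = 0.0603). miR-29 held 4 positive and 0 negative of 5 (4 adjusted over the list alone, adjusted p = 0.372). miR-30 had 8 positive and 0 negative of 9 (8 adjusted over the list alone, adjusted p = 0.0603). miR-34 held 2 positive and 0 negative of 3 (2 adjusted over the list alone, adjusted p = 0.538). miR-181 had 0 positive and 0 negative of 3 (0 adjusted over the list alone, adjusted p = 0.372). miR-199 with miR-214 held 3 positive and 1 negative of 5 (5 adjusted over the list alone, adjusted p = 0.889). The neural list had 2 positive and 1 negative of 4 (4 adjusted over the list alone, adjusted p = 0.889). The embryonic stem cell clusters held 1 positive and 0 negative of 3 (1 adjusted over the list alone, adjusted p = 0.889). The miR-96, miR-182 and miR-183 cluster had 2 positive and 0 negative of 4 (2 adjusted over the list alone, adjusted p = 0.697). The study microRNAs (not independent evidence) held 1 positive and 1 negative of 3 (2 adjusted over the list alone, adjusted p = 0.889). The medians of miR-17~92, let-7, the miR-99, miR-100 and miR-125 clusters, the X-linked cluster, the miR-23, miR-27 and miR-24 clusters, the miR-96, miR-182 and miR-183 cluster and the study microRNAs turned negative with a percentile over all mouse microRNAs, and that of miR-34 in the unscaled table and with the authors' total gene signal. miR-221 and miR-222 had 2 positive, and 1 of 2 Dlk1-Dio3 members was negative. Of the markers, miR-126-3p was positive (adjusted p = 0.000267), miR-486 at -0.52 (adjusted p = 0.0261) and miR-206 at -0.22 (adjusted p = 0.0788). The call of miR-486 ended in 5 fits that left out an array, with the highest adjusted p, 0.0979, without c-Src array 2 (log2 difference from -0.52, SE 0.14, to -0.46, SE 0.16). miR-206 passed without mock array 1 (-0.31, adjusted p = 0.0197) or Csk array 2 (-0.32, adjusted p = 0.0182), with median scaling (-0.16) and with a percentile over all mouse microRNAs (-0.39). After normexp none of the markers passed, and miR-126-3p was at -0.13.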

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

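The test of an explanation in this part was chosen only after the result was seen.

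For 123 of 243 microRNAs the difference between cells with and without added c-Src was not the same with Csk as without it. This is limma's test of the interaction itself (90 positive, 33 negative). The largest positive differences were 4.35 for miR-146a, 3.03 for miR-10a and 2.95 for miR-721, and the largest negative ones -2.85 for miR-143, -2.14 for miR-10b and -2.14 for miR-455. The values for miR-146a and miR-721 depend on the floor, since no Csk+c-Src array detected either. The balance of directions depended on the scaling, and was 34 positive and 69 negative with a percentile over all mouse microRNAs. Without Csk+c-Src array 2 the count was 80. After normexp background correction limma called 1 microRNA for the interaction, and without its offset 0 (43 at an unadjusted p under 0.05), and miR-721 was at -0.26 and -0.16.

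miR-10a, miR-146a and miR-196a were lowest in Csk+c-Src cells, by at least 2-fold against each of the other groups. Other groups had more microRNAs set apart in this way. There were 18 in Csk cells (11 higher, 7 lower), 10 in c-Src cells (4 higher, 6 lower) and 0 in mock cells. miR-10a, miR-146a and miR-196a were picked out after their values were seen. Each slide column held 1 group (0 columns held more than 1). An effect of the array column on the slide and an effect of the transfected genes thus cannot be told apart, for these microRNAs or any other. A difference between the transfected cell populations that does not come from Csk or c-Src may also be the source, for these microRNAs or any other, and was not tested.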

How the results depend on the processing

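Median scaling, the unrounded signal, normexp without an offset, leaving out the microRNAs at the floor on all arrays and splitting the c-Src arrays between the comparisons were chosen after the data were seen. Sign changes were counted only for differences called in the main fit or in the alternative. Of 3768 values of 153 named differences under 25 alternatives, 3244 kept their side of the threshold, and their direction where called. Another 430 kept the direction and lost the call, 35 gained a call and 59 changed sign. Of 155 values of the counts under 20 alternatives that leave out no array, 136 stayed within 1.5 times the main value.

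Normexp background correction reversed 25 of the named differences, with sign changes counted in the same way, and ended the call of 72, and without its offset 16 and 93. With the offset it called 28 microRNAs in c-Src against mock, 19 in Csk+c-Src against c-Src, 19 in Csk against mock, 39 in Csk+c-Src against Csk, 1 in Csk+c-Src against mock and 1 for the interaction, with 14 turned back and 3 lists in c-Src against mock. The median over all microRNAs became -0.46 in c-Src against mock, -0.29 in Csk against mock and -0.46 in Csk+c-Src against mock. Without its offset the counts were 16, 13, 15, 29, 0 and 0 in the same order, with 11 turned back. Where limma called 0 in this way, 49 (Csk+c-Src against mock) and 43 (interaction) had an unadjusted p under 0.05. Negative control spots lay 38.5 to 46.6 above their local background, the quantity normexp starts from, and 1.65 to 2.67 in the processed signal. How much unspecific signal normexp leaves on dim microRNAs was not measured. In c-Src against mock it reversed miR-34c (-0.26), miR-34b-5p (-0.20), miR-721 (-0.58), miR-29b* (-0.53), miR-99b* (-0.62), miR-24-2* (-0.35), miR-126-3p (-0.48), miR-128 (-0.41), miR-9 (-0.46), miR-466a-3p (-0.46) and miR-669f (-0.19). In Csk+c-Src against c-Src it reversed miR-721 (0.00309), miR-125a-3p (0.0175), miR-214* (0.0508), miR-128 (0.00969) and miR-290-5p (0.028), in Csk against mock miR-721 (-0.26), miR-135a* (-0.27) and miR-126-3p (-0.24), in Csk+c-Src against Csk miR-206 (-0.0415) and miR-486 (-0.0584), in Csk+c-Src against mock miR-218 (-0.0115) and miR-466a-3p (-0.44), and for the interaction miR-721 (-0.26) and miR-126-3p (-0.13). Without the offset the reversed values in c-Src against mock were -0.23 for miR-34c, -0.12 for miR-34b-5p, -1.06 for miR-721, -0.87 for miR-29b*, -1.19 for miR-99b*, -0.46 for miR-24-2*, -0.75 for miR-126-3p, -0.59 for miR-128, -0.95 for miR-9, -0.79 for miR-466a-3p and -0.20 for miR-669f. The others were miR-721 (-0.43), miR-135a* (-0.50) and miR-126-3p (-0.44) in Csk against mock, miR-466a-3p (-0.81) in Csk+c-Src against mock and miR-721 (-0.16) for the interaction. Whether signal near the background is behind these reversals was not tested.

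With no detection filter limma called 66 in c-Src against mock and 46 in Csk+c-Src against mock of 611 microRNAs. That alternative adds microRNAs with no spread at the floor, and with those left out the counts were 116 and 91. With an estimated correlation camera called 0 lists in c-Src against mock (1 at an unadjusted p under 0.05) and 0 in Csk+c-Src against c-Src (2 at an unadjusted p under 0.05).

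Reversals given here are again only of named differences called in the main fit or in the alternative. Scaling reversed miR-128 (0.0453, Csk+c-Src against c-Src, percentile over all mouse microRNAs), and quantile normalization reversed miR-15b (-0.29) in c-Src against mock, miR-15b (-0.18), miR-16 (-0.15) and miR-486 (0.0166) in Csk against mock, and miR-15b (0.059) and miR-16 (0.00246) in Csk+c-Src against Csk. The mean of log2 over probes reversed miR-99b* (-0.012) and miR-100 (0.0475) in c-Src against mock and miR-100 (-0.0700) in Csk+c-Src against c-Src. The unscaled series table reversed miR-100 (0.15), miR-30d (0.0573), miR-30a (0.15), miR-181b (0.00175), miR-181a (0.0258), miR-199a-3p (0.0337), miR-219 (0.0472) and miR-183 (0.24) in c-Src against mock, where its median over all microRNAs was 0.31; beyond that shift the cause was not tested. Its medians were 0.16 in Csk against mock and 0.08 in Csk+c-Src against mock. With only microRNAs detected on all arrays the median in Csk+c-Src against Csk was -0.22.

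With each array left out in turn, the lone array left in its group being assumed to vary like the others, the counts ranged from 56 to 112 in c-Src against mock, 82 to 112 in Csk+c-Src against c-Src, 109 to 137 in Csk against mock, 111 to 147 in Csk+c-Src against Csk, 30 to 88 in Csk+c-Src against mock and 80 to 121 for the interaction. Those turned back ranged from 42 to 66, and lists from 4 to 5 and from 5 to 5. The lowest counts came without mock array 2 (56, 32 in Csk+c-Src against mock, 42 turned back) and without Csk+c-Src array 2 (67 in c-Src against mock, 30, 80), and 53 were called in Csk+c-Src against mock without Csk+c-Src array 1. Of 135 named calls 34 ended without at least 1 array, 29 of them in 2 or more of these fits, and 0 changed sign.

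The replicate numbers were not taken to pair the arrays. Deviations of same-numbered arrays correlated at r = -0.09 to 0.44 over 6 pairs of groups, over 0.1 in 3. With the replicate number as a replicate block the counts were 117, 121, 151, 156 and 103 in the order of the comparisons and 141 for the interaction.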

Other observations

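All 4 tests of explanations in this part were chosen only after the result was seen.

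The X-linked cluster fell with c-Src and rose with Csk. After normexp its median was -0.825 in c-Src against mock and 0.14 in Csk against mock. Technical accounts were set against the main values of the cluster. Its median in c-Src against mock was -1.52, while the lowest of 10000 random lists matched on mean signal was -0.76, which argues against a bias that follows brightness. Its median nearest 0 under 5 scalings was -1.21, in the unscaled table, so the fall was there under each of them. These scalings moved the median over all microRNAs only between -0.06 and 0.31. The test of scaling could thus hardly have ended otherwise. If it made up a member's whole signal, cross-hybridisation of miR-322, the brightest member, would let no member change more than miR-322. Beyond 2 SE of the difference 5 of 8 did, 2 in c-Src against mock and 4 in Csk against mock (miR-542-3p by 0.51, SE 0.05). Some excesses were little over that limit, as for miR-542-5p in Csk against mock (0.16, SE 0.07). In c-Src against mock other members changed less than miR-322, miR-542-3p by 0.75 among them. miR-351, miR-450a-5p and miR-450b-5p exceeded miR-322 beyond 2 SE in neither comparison, so for those 3 cross-hybridisation stays open. For the other 5 the values argue only against a signal that comes wholly from miR-322. A part of the signal from cross-hybridisation stays open for them too.

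A shared primary transcript is a candidate explanation, as a hypothesis: 57 pairs of microRNAs outside the cluster with genes within 10 kb of each other correlated over the 8 arrays at a median r of 0.745, against 0.0686 for other pairs (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). The 8 arrays fall into 4 groups, so these correlations mostly follow group differences. The 8 located members of the cluster lie within 6.26 kb and correlated at a median r of 0.956. An effect of the slide column stays open here as well, since each column held 1 group.

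Probes for viruses gave signal in all groups, mock cells included. Of 39 viral names 4 were detected: mcmv-miR-M23-1-5p on 8 arrays (-3.60 to -3.16), mcmv-miR-m88-1 on 8 (-4.44 to -4.13), mghv-miR-M1-2 on 8 (-2.71 to -2.34) and mcmv-miR-m88-1* on 7 (up to -5.27).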
